A study of Mus musculus with 24 samples.

How the data were processed

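The series holds 24 ChIP-seq and input samples of mouse TgSpi1 erythroleukaemic cells. Peak lists of 4 of its groups were used: H3K27ac and H3K4me1, each without and with 48 h of doxycycline. The samples for H3K27me3, SPI1, RNA polymerase II, input DNA and the entinostat and DMSO treatments were not analysed here. Groups were taken from the sample titles. Per the series' design text, each H3K27ac list is linked to replicates 1 and 2 together, and the H3K4me1 lists hold replicate 1. Nothing in the sources used here ties a replicate number to a shared culture or day.

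The submitters' processing notes name bcl2fastq 2.17.1.14, BWA and the build mm10. The peak caller, its thresholds and the way the 2 H3K27ac replicates were combined are not given in the sources used here. The deposited H3K27ac lists give positions and a width in bp that equals end minus start plus 1 in every line. Their last column has the value 2 throughout and was not used to rank peaks. The deposited H3K4me1 lists give a score per peak by the authors, whose scale is not stated, and a further column below 0.01 that the authors may have meant as a p-value or q-value. That score followed peak width closely (Spearman rho 0.984 in each list) and was used only to rank peaks within a list. Starts lay on a grid of 50 bp in all lists, and coordinates were read as 1-based with both ends included. H3K27ac peaks were as narrow as 3 bp, and 1171 untreated and 663 treated ones were under 200 bp. Where a deposited H3K27ac list holds only stretches found in both replicates, its peak widths, numbers and single-condition peaks would also depend on how well the replicates match, and this could not be settled here. No read counts were used, so depth is unknown. A list called from more reads can hold more or wider peaks, and covered length moves with how much was called, not with signal height.

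Peaks on assembled chromosomes were kept. Gene positions came from a RefSeq gene table on GRCm38.p6, the assembly that mm10 names, with 21887 protein-coding genes. This table has neither strand nor exons. The planned windows at the 5' end were therefore replaced by windows at both annotated ends of each gene, and the planned promoter, exon and intron classes by within 1 kb of a gene end, gene body and intergenic. The planned motif comparison and the comparison of any start site with the gene's 5' end were not run. Overlaps and lengths were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and checked against bedtools 2.31.1 on the real lists, with equal numbers under both overlap rules compared. Figures were drawn with matplotlib 3.10.9.

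A peak counted as shared when it overlapped the other list of its mark by at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error over peaks only. Ratios carry a standard error from leaving out each chromosome in turn. The overlap expected by position was taken from 100 shuffles of the peaks on their own chromosomes. For each gene, the bp covered by peaks within 5 kb of either end were summed per list. For 15 gene lists, the mean of treated minus untreated was set among 10000 random lists of the same size, matched in 10 bins of mean covered length, and its percentile describes these lists only. With 30 combinations of list and mark, 6 lay outside the central 95%. The symbols Ahsp, Mx1 and Mx2 had no match in the gene table. Several comparisons, settings and genes were added after results were seen, as stated below. The gene lists, the planned comparisons and the rules for naming genes and peaks were fixed before the data were examined. The rule took, per mark, the 10 genes with the largest difference in each direction with no overlapping windows, the 2 leading members of each list in each direction, and Spi1; for peaks it took the 5 widest of each condition alone. Some genes that this rule takes are not reported here.

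The calculation was tested on simulated data: the real untreated list against a copy with peaks dropped at random and edges moved slightly. Of genes given 2000 bp of added coverage, 76% in H3K27ac and 89% in H3K4me1 passed the 99th percentile of the other genes, and with 5000 bp 100% did in both. The real lists differed more, with 99th percentiles of 2266 bp in H3K27ac and 3692 bp in H3K4me1. A gain of 2000 bp lies below both, so these shares do not hold for the real lists. Of 100 random lists with nothing added, 4 in H3K27ac and 1 in H3K4me1 lay outside the central 95%. Those lists were themselves drawn at random, so this checks the calculation only. Alternatives were the better 50% of each list (by the authors' score in H3K4me1 and by width in H3K27ac), equal peak numbers, peaks within 1 kb merged, autosomes alone, stricter overlaps, other windows, scaled lengths, peaks of at least 200 bp, gene bodies with flanks, the erythroid list without globin genes, and each list without its member of largest change. No count model, replicate comparison or p-value was possible with 1 list per mark and condition.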

Results

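Chromatin was mapped by ChIP-seq in mouse erythroleukaemic cells of bone marrow origin that carry a Spi1 transgene and overexpress SPI1 (also called PU.1), an ETS family transcription factor of myeloid and B cells. Doxycycline for 48 h induced a short hairpin RNA against Spi1, and untreated cultures served as the control. The comparison asks how H3K27ac and H3K4me1 differed between cultures with and without this induction. H3K27ac is a mark of active promoters and enhancers, and H3K4me1 one of enhancers whether active or not. No group of the series is labelled as doxycycline without the hairpin. Effects of the drug or of hairpin expression therefore cannot be told apart from those of lower SPI1. There were 4 peak lists, 1 per mark and condition. The H3K27ac lists each stand for replicates 1 and 2 together, and the H3K4me1 lists each hold 1 replicate. No value below therefore has a replicate error, and every difference between conditions is a difference between lists, without a test. The read depth behind each list is unknown, and so is the way the H3K27ac replicates were combined, on which peak widths and numbers depend.

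At Spi1 itself (chromosome 2, 91082374 to 91115759), H3K27ac peaks covered 3265 bp within 5 kb of the gene ends in the untreated list and 2412 bp in the treated list. H3K4me1 covered 7015 bp and 8412 bp. Within 20 kb either side of the gene, the untreated list had 8 H3K27ac peaks over 6974 bp and the treated list 7 peaks over 6871 bp. The untreated peak at 91082549 to 91083451, inside the gene and within 1 kb of an annotated end, had no counterpart in the treated list. In H3K4me1 there were 17 untreated peaks over 23101 bp and 13 treated peaks over 28039 bp. Among genes of similar covered length, the change at Spi1 stood at the 13.2 percentile for H3K27ac and at the 75.2 percentile for H3K4me1. The cells carry a Spi1 transgene, and the lists cannot tell whether reads from it were placed at this gene. The hairpin acts on the transcript, so these marks do not measure the knockdown.

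Genes of red cell structure and haem synthesis had, on average, more bp covered by H3K27ac and H3K4me1 peaks in the treated lists. Of 49 erythroid membrane, globin and haem genes, 39 had a longer H3K27ac length in the treated list, 9 a shorter one and 1 an equal one. Their mean was 3909 bp untreated and 5063 bp treated, a difference of 1153 bp. In H3K4me1, 42 were longer and 7 shorter, with means of 7862 bp and 9805 bp. When treated H3K4me1 lengths were scaled to the untreated total, 36 were longer and 13 shorter. Hba-a1, an adult alpha-globin gene (chromosome 11, 32283672 to 32284486), had no H3K27ac untreated and 6109 bp treated. Its near-identical copy Hba-a2 had 0 bp and 3156 bp, and reads may be shared between these copies. Alas2, the first enzyme of haem synthesis in erythroid cells (chromosome X, 150547417 to 150570622), went from 1003 bp untreated to 4909 bp treated in H3K27ac and from 9729 bp to 14629 bp in H3K4me1. Car2, a carbonic anhydrase, differed in H3K4me1, with 8442 bp and 15245 bp, and was alike in H3K27ac, with 9604 bp and 9554 bp. Members in the other direction were Xpo7, a nuclear exporter, with 3157 bp and 1588 bp of H3K27ac, Car1, with 6490 bp and 5790 bp, and Bnip3l, a mitophagy receptor, with 7550 bp and 6331 bp of H3K4me1. H3K27ac within 1 kb of a gene end appeared in the treated list alone at 5 members, Hba-a1, Hba-a2, Hbb-bs, Slc4a1 and Alas2, and in the untreated list alone at 0. Hbb-bs and Slc4a1 were singled out after their values were seen. The mean difference of the list exceeded that of each of 10000 random gene lists matched on covered length, in both marks (percentile 100). With the 7 globin genes left out, the means were 947 bp and 1801 bp and the percentile was 100 in both marks.

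Myeloid genes went the other way. Of 50 such genes, 19 had a shorter H3K27ac length in the treated list, 4 a longer one and 27 an equal one, with means of 1256 bp untreated and 1002 bp treated. In H3K4me1, 29 were shorter, 11 longer and 10 equal, with means of 4243 bp and 3650 bp. Fes, a tyrosine kinase of myeloid cells (chromosome 7, 80377758 to 80387954), had 5100 bp of H3K27ac untreated and 1306 bp treated. Laptm5, a lysosomal membrane protein of blood cells, had 3053 bp and 753 bp of H3K27ac and 9092 bp and 5848 bp of H3K4me1. Cyba, a subunit of the phagocyte NADPH oxidase, had 5206 bp and 1853 bp of H3K4me1. The 4 members with longer H3K27ac were Ncf4, another oxidase subunit, with 0 bp and 2587 bp, Cebpd, with 0 bp and 903 bp, Egr1, with 4901 bp and 4998 bp, and Egr2, with 1603 bp and 2203 bp. Egr1 and Egr2 were named after their values were seen. H3K4me1 was longer in the treated list at Btk, with 9652 bp and 12663 bp, and at Cebpb, with 5459 bp and 7756 bp. Near a gene end, 3 members had H3K27ac in the untreated list alone and 2 in the treated list alone, and for H3K4me1 the numbers were 8 and 0. The mean difference stood at the 0.11 percentile of matched random lists for H3K27ac (-254 bp) and at percentile 0 for H3K4me1 (-593 bp).

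**Figure D1:**
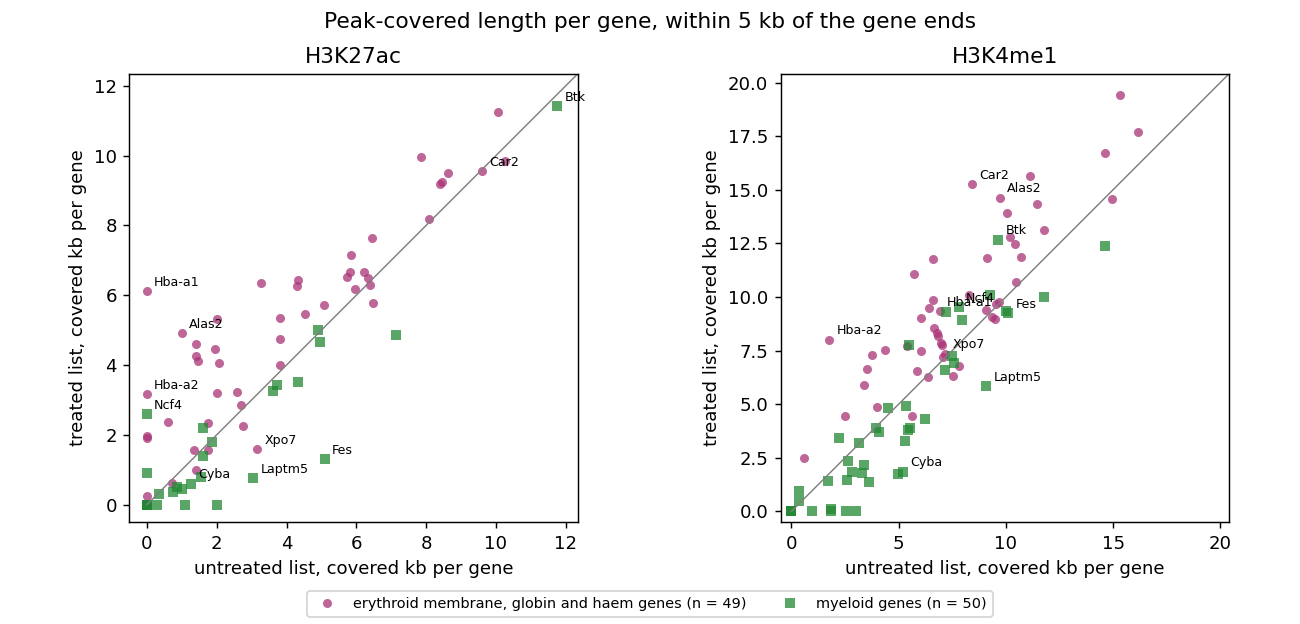
Peak-covered length within 5 kb of the ends of each gene, in kb, in the untreated list (horizontal axis) and the treated list (vertical axis), for H3K27ac (left) and H3K4me1 (right). Each point is a gene, circles for the 49 erythroid membrane, globin and haem genes and squares for the 50 myeloid genes, and the line marks equal length: 39 circles lie above it in H3K27ac, and 19 squares below.

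Of the other lineage lists, megakaryocyte genes and B cell genes stood outside the central 95% of random lists in 1 mark each. The 18 megakaryocyte genes had a mean H3K27ac difference of 475 bp (99.2 percentile), with a median of 0, and 7 were longer. It was led by the neighbouring platelet chemokine genes Ppbp, with 4124 bp untreated and 8121 bp treated, and Pf4, with 4309 bp and 7808 bp, whose windows share peaks. Gp5, a platelet glycoprotein, had 6153 bp and 4756 bp. With the wider 50% of each H3K27ac list the megakaryocyte mean was 359 bp, inside the central range at the 94.1 percentile. Without Ppbp it was 268 bp at the 93.5 percentile. Pf4 stayed in the list for that value, so the peaks in the shared part of the windows still counted. A mean without both genes was not computed. The 17 B cell genes had a mean H3K4me1 difference of -536 bp (0.19 percentile), with a median of 0. Rag2, a recombinase subunit, had 6171 bp and 3459 bp, while Cd72 had 6690 bp and 9791 bp. The B cell mean was -362 bp at the 8.07 percentile with windows of 20 kb and 9.18 bp at the 22.4 percentile over gene bodies with 5 kb either side.

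Erythroid transcription factor genes did not stand apart. Of 15, 10 had shorter H3K27ac in the treated list, with a mean of -209 bp (34.0 percentile), and 12 had longer H3K4me1, with a mean of 923 bp (77.1 percentile). With treated H3K4me1 lengths scaled to the untreated total, 10 were longer and the mean was 277 bp (72.1 percentile). Gata1, the main erythroid GATA factor (chromosome X), had 4610 bp and 2913 bp of H3K27ac and 14872 bp and 16857 bp of H3K4me1. Nfe2 had 12559 bp and 11003 bp of H3K27ac, Gfi1b had 9675 bp and 10378 bp, and Klf3 had 6229 bp and 9282 bp of H3K4me1. With H3K27ac lengths scaled in the same way, 7 of the 15 factors were longer and 8 shorter, and with windows of 20 kb their mean was 196 bp. Of 27 stem and progenitor genes, 14 had shorter H3K27ac, with Meis1 at 5209 bp and 3556 bp, and the mean of -255 bp stood at the 7.62 percentile. In H3K4me1 the list stood at the 57.0 percentile. Over gene bodies with 5 kb either side, it stood at the 0.39 percentile in H3K27ac and at the 1.22 percentile in H3K4me1.

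**Figure D2:**
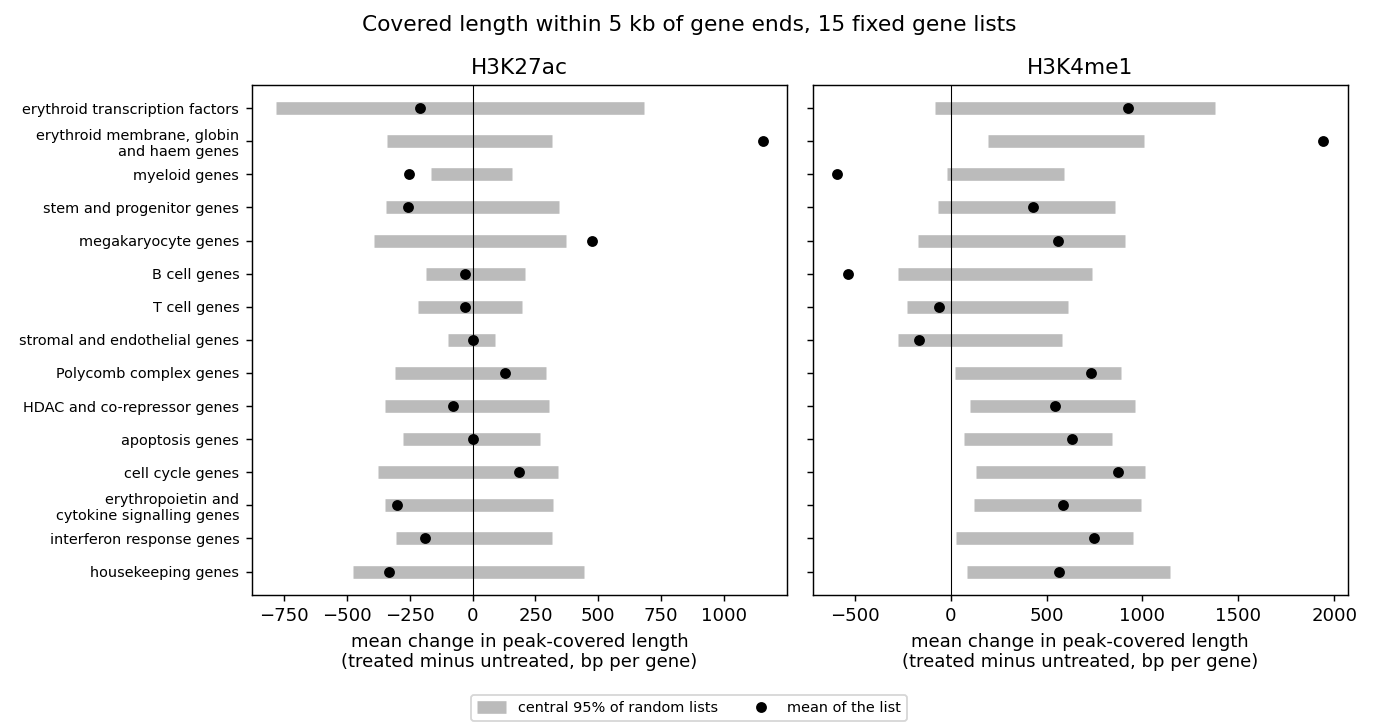
Mean change in peak-covered length per gene (treated minus untreated, in bp) for 15 gene lists, in H3K27ac (left) and H3K4me1 (right). Points are the list means and grey bars the central 95% of 10000 random lists matched on covered length: 3 points lie outside the bar in each mark, with the erythroid membrane, globin and haem genes at 1153 bp and 1943 bp and the myeloid genes at -254 bp and -593 bp.

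The lists for regulators, signalling and cell fate lay inside the central range in both marks with windows of 5 kb. Apoptosis genes had a mean H3K27ac difference of 2 bp (54.3 percentile), with 15 longer and 18 shorter of 43 and a sign that changed with the processing, and 632 bp in H3K4me1 (82.1 percentile), with 27 longer and 12 shorter. With H3K4me1 lengths scaled to the same total these were 233 bp (82.2 percentile), 21 and 18. Among the apoptosis genes, Bcl2l11, which encodes the BH3-only protein BIM, had 2856 bp and 4252 bp of H3K27ac and 8508 bp and 12125 bp of H3K4me1. Fasl, a death receptor ligand, had 0 bp and 2147 bp of H3K27ac, and Tradd, a death receptor adaptor, had 5008 bp and 3152 bp. The survival gene Mcl1 had 7502 bp and 5390 bp. Cell cycle genes stood at the 87.6 and 90.9 percentiles, with 25 of 39 longer in H3K27ac. Their H3K27ac mean of 185 bp rested on Btg2, without which it was -20.4 bp (51.2 percentile), and over gene bodies with 5 kb either side it was -308 bp. E2f8, an E2F repressor, had 12779 bp and 8409 bp of H3K27ac, and Ccnd3, cyclin D3, had 13525 bp and 11175 bp. Genes of erythropoietin and cytokine signalling had a mean H3K27ac difference of -301 bp (4.71 percentile), with 22 of 39 shorter. It was -151 bp (21.5 percentile) without Grb2 and -65.4 bp (19.9 percentile) with windows of 2 kb. In H3K4me1 the mean was 585 bp (56.3 percentile), with 25 longer and 12 shorter, and 76.2 bp, 18 and 20 with scaled lengths. Over gene bodies with 5 kb either side the list stood below the central range, at the 0.47 percentile in H3K27ac and 0.6 in H3K4me1, and with windows of 20 kb at 2.22 in H3K4me1. Among these, Stat3 had 9229 bp and 5970 bp, and Socs3, a feedback inhibitor of cytokine receptors, had 1856 bp and 5897 bp. Polycomb complex genes stood at the 83.0 and 89.6 percentiles, with Ezh1 at 2106 bp and 4056 bp of H3K27ac and 10469 bp and 13500 bp of H3K4me1. Ezh2 had 3003 bp and 3303 bp of H3K27ac and 8113 bp and 6338 bp of H3K4me1. HDAC and co-repressor genes stood at the 37.0 and 54.5 percentiles, with Hdac3 at 6884 bp and 4859 bp of H3K27ac and Mta1 at 3106 bp and 5406 bp. Interferon response genes stood at the 12.2 and 86.8 percentiles, with Irf5 at 2056 bp and 553 bp of H3K27ac and Ifit1 at 3609 bp and 8276 bp of H3K4me1. Of 28 housekeeping genes, the control list, 19 had shorter H3K27ac, with Eef2 at 10162 bp and 6862 bp. Their mean H3K27ac difference was -331 bp, larger in bp than that of the myeloid genes, from a mean of 5270 bp untreated. They stood at the 9.58 and 43.3 percentiles, T cell genes at 42.6 and 11.7, and stromal and endothelial genes at 55.9 and 7.18, for H3K27ac and H3K4me1 in that order. Over all 21887 protein-coding genes the mean H3K4me1 difference was 275 bp and the mean H3K27ac difference -4.78 bp, and with treated lengths scaled to the same total these were 30.7 bp and 5.77 bp. Of genes with unequal H3K4me1 length, 63.5% were longer in the treated list, and 51.4% with lengths scaled to the same total.

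The gene with the largest H3K27ac difference upward was Btg2, an antiproliferative gene (chromosome 1, 134074865 to 134079155), with 2909 bp untreated and 10915 bp treated. Erfe, which encodes the erythroid hormone erythroferrone (chromosome 1, 91366305 to 91374217), had 2859 bp and 10859 bp, and its H3K4me1 went from 6359 bp to 12522 bp. Msantd1, next to Htt, had 4465 bp and 11872 bp, and Kmt5c, a histone H4 lysine methyltransferase, had 5228 bp and 11972 bp. Eral1, a mitochondrial ribosome assembly factor, had 2556 bp and 9629 bp. Sh3tc2 (chromosome 18, 61952928 to 62015719) had no H3K27ac untreated and 5265 bp treated, and its H3K4me1 was 5639 bp and 16087 bp. Slc30a10, a manganese exporter, had 5662 bp and 10770 bp of H3K27ac, Nacad 1603 bp and 6847 bp, and Ehd1 8224 bp and 13465 bp. In H3K4me1 the largest difference upward was at Acsm5, with 753 bp and 12121 bp, followed by Sh3tc2, Chst10, with 2918 bp and 11540 bp, and the phosphatase gene Dusp8, with 6101 bp and 14555 bp.

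In the other direction, Cmtm7 (chromosome 9, 114756836 to 114781993) had 9807 bp of H3K27ac untreated and 1503 bp treated. Ccl9, a chemokine gene (chromosome 11, 83572917 to 83578636), had 6065 bp and 0 bp, with 12756 bp and 9521 bp of H3K4me1. Grb2, an adaptor of receptor tyrosine kinase signalling, had 10408 bp and 4402 bp. Fam189b had 9374 bp and 3312 bp, Heg1 9037 bp and 4262 bp, Arrb2, a beta-arrestin, 6306 bp and 1653 bp, and Rhog 9865 bp and 5259 bp. Evi2b had 6623 bp and 2156 bp, Man2a2, the neighbour of Fes, 7385 bp and 2909 bp, and Mns1 9832 bp and 4776 bp. In H3K4me1 the largest differences downward were at Tmem176b, with 8611 bp and 2916 bp, Ncbp3, with 12062 bp and 6475 bp, Tnfsf14, with 9112 bp and 3559 bp, and Traf1, with 9873 bp and 4514 bp. Tmem176b also had 2653 bp of H3K27ac untreated and 0 bp treated.

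**Figure D3:**
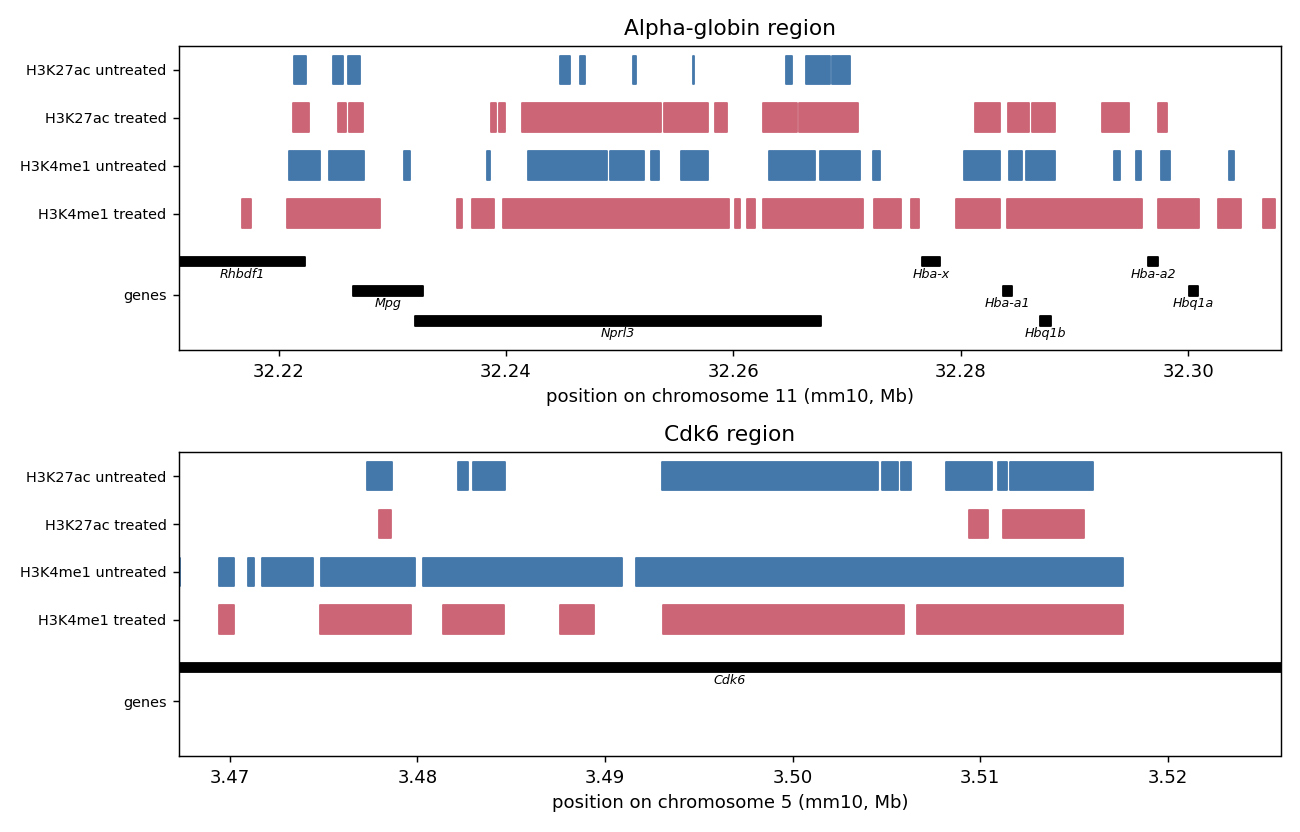
Peaks of the 4 lists (blue untreated, red treated) and RefSeq genes (black) by position in Mb on chromosome 11 around the alpha-globin genes (top) and on chromosome 5 inside Cdk6 (bottom). In the upper region H3K27ac peaks cover 8830 bp untreated and 38845 bp treated between 32221249 and 32298101, and in the lower one 23777 bp and 6009 bp between 3477299 and 3516001.

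Both treated lists held fewer and wider peaks than the untreated lists. H3K27ac had 28902 untreated and 23341 treated peaks on assembled chromosomes, a ratio of 0.808 ± 0.0050 (SE over 21 chromosomes left out in turn, not a replicate error). Their median widths were 1003 bp and 1353 bp, and the covered lengths 41.5 Mb and 41.2 Mb (ratio 0.993 ± 0.0055). H3K4me1 had 119362 and 101388 peaks, a ratio of 0.849 ± 0.010, with median widths of 903 bp and 1153 bp and covered lengths of 184 Mb and 195.4 Mb (ratio 1.06 ± 0.0050). With the lists limited to equal peak numbers, the covered length ratio was 1.03 in H3K27ac, above 1 rather than below it. The number ratio was lowest among narrow peaks: for peaks under 500 bp it was 0.405 in H3K27ac and 0.374 in H3K4me1, and for peaks of at least 2000 bp 1.11 and 1.10. The widest H3K27ac peak found in the untreated list alone spanned 11.5 kb inside Cdk6, a G1 kinase gene (chromosome 5, 3493049 to 3504551). Other such peaks lay in Rnf130, 4753 bp wide, Tcf12, 4203 bp, and Sipa1l1, 4153 bp. The widest in the treated list alone lay 13357 bp from Muc5ac (chromosome 7, 141769099 to 141775601), followed by peaks in Lpcat1, Supt3, Col18a1 and Gda. In H3K4me1, the widest untreated-only peak was 7.70 kb, 37806 bp from Abhd17c, and the widest treated-only peaks, of 5.30 kb each, lay in Mgll and 1489 bp from Acsm2.

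Of untreated H3K27ac peaks, 72.6% (95% exact interval 72.1 to 73.1%) overlapped a treated peak by at least 1 bp, and 82.9% (82.5 to 83.4%) of treated peaks overlapped an untreated one. In H3K4me1 the shares were 73.3% (73.1 to 73.6%) and 79.2% (79.0 to 79.5%). Peaks of the same widths placed at random on their chromosomes overlapped in 2.85% and 3.31% for H3K27ac and 12.3% and 13.5% for H3K4me1. This left 7928 untreated-only and 3983 treated-only H3K27ac peaks, and 31842 and 21054 H3K4me1 peaks. These were narrow, with median widths of 453 bp and 553 bp in both marks, against 1403 bp and 1603 bp for shared H3K27ac peaks. The intervals cover counting error over peaks only. With equal peak numbers the order turned, with 80.8% of untreated and 78.4% of treated H3K27ac peaks shared, and 80.4% and 75.5% in H3K4me1. Under a reciprocal overlap of 50% of both peaks, 49.9% of untreated and 61.8% of treated H3K27ac peaks were shared, and 49.6% and 58.4% in H3K4me1.

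**Figure D4:**
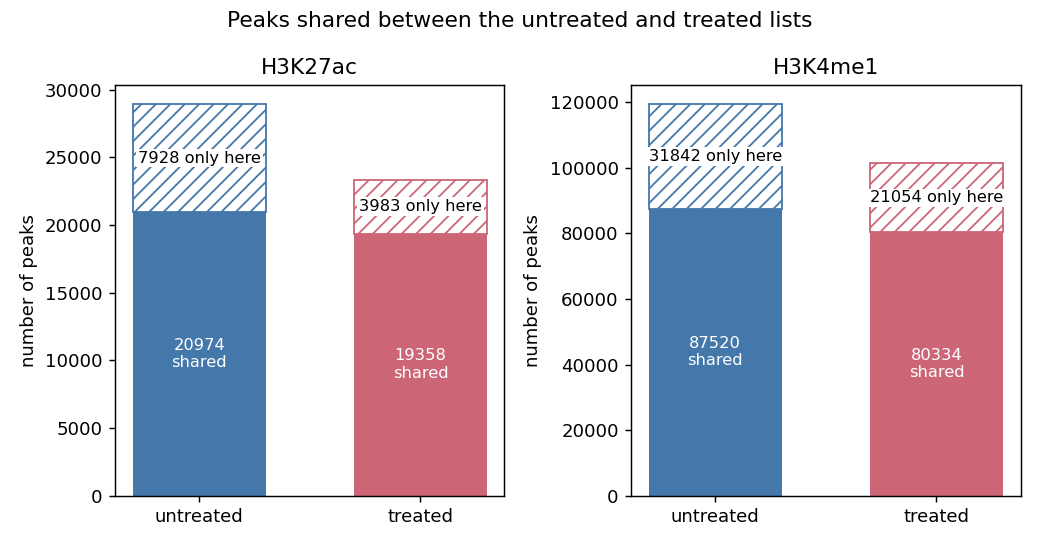
Number of peaks per list (bars from 0), for H3K27ac (left) and H3K4me1 (right), untreated in blue and treated in red. The filled part counts peaks that overlap a peak of the other condition by at least 1 bp, and the hatched part those that do not, which number 7928 and 3983 in H3K27ac and 31842 and 21054 in H3K4me1.

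Peaks of a single condition lay near gene ends less often than shared peaks. Shared peaks were wider, and a wider peak overlaps such a window more readily. The share expected by position was not computed. Within 1 kb of an annotated gene end lay 9.26% (8.63 to 9.92%) of untreated-only and 8.59% (7.73 to 9.50%) of treated-only H3K27ac peaks, against 46.6% and 47.4% of the shared ones. Gene bodies held 58.9% and 55.2% of them, and the remaining 31.8% and 36.3% were intergenic. For H3K4me1 the shares near a gene end were 5.03% (4.797 to 5.28%) and 4.74% (4.45 to 5.03%), against 22.2% and 23.8% of shared peaks. Few genes had a peak near their ends in a single list: 9815 genes had H3K27ac there in both lists, 366 in the untreated list alone and 212 in the treated list alone. For H3K4me1 the numbers were 12709, 537 and 433. With equal peak numbers the order turned in both marks, with 239 genes in the untreated list alone and 353 in the treated list alone for H3K27ac, and 391 and 516 for H3K4me1. With gene ends taken as 500 bp, the H3K4me1 order also turned, to 585 and 871. In the wider 50% of each H3K27ac list, 1138 genes had it in the untreated list alone and 375 in the treated list alone. Of the peaks, 29.7% of untreated-only and 21.6% of treated-only ones lay near a gene end. The width cut was the median of each list, 1003 bp untreated and 1353 bp treated. The untreated list thus kept more and narrower peaks, which by itself adds to its number of genes. Genes with H3K27ac near an end in the untreated list alone included Kit, Hoxa9, Ccnd1 and Pik3cd, and those in the treated list alone included Bcl2, Itgb3 and Mecom. Within 5 kb of the ends, Hoxa9 had 853 bp untreated and 803 bp treated, so H3K27ac was hardly changed there. Ccnd1 had 2559 bp and 803 bp, Pik3cd 4345 bp and 1486 bp, and Mecom 353 bp and 653 bp, so these too had H3K27ac in both lists. Kit, Hoxa9, Ccnd1, Bcl2 and Itgb3 were named after their status was seen.

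The marks were then set against each other. Of untreated H3K4me1 peaks, 22.5% (22.3 to 22.7%) overlapped an untreated H3K27ac peak, and 23.2% (22.9 to 23.4%) of treated ones a treated H3K27ac peak; the order turned with peaks within 1 kb merged (23.3% and 22.7%), with equal peak numbers (24.2% and 23.2%) and with overlaps of 50% of the peak (6.68% and 6.17%) or of both peaks (2.98% and 2.71%). Over 1 kb from gene ends the shares were 12.9% (12.7 to 13.1%) and 11.5% (11.3 to 11.8%). Nearly every H3K27ac peak lay over H3K4me1 of its own condition, 99.02% untreated and 99.5% treated. H3K27ac peaks of a single condition lay mostly over H3K4me1 that was present in both: 95.9% (95.5 to 96.4%) of untreated-only and 94.1% (93.4 to 94.8%) of treated-only peaks. H3K4me1 of the same single condition underlay 2.54% and 3.92% of them. For shared H3K27ac peaks, 99.2% of untreated and 99.4% of treated ones lay over H3K4me1 of both lists. H3K4me1 of the same list alone underlay 0.048% and 0.346% of these shared peaks, a smaller share than for single-condition peaks. Under a reciprocal overlap of 50% of both peaks, the shares of single-condition H3K27ac peaks over H3K4me1 of both lists were 5.33% and 6.60%. Across the 11688 genes covered in both marks, the changes in covered length had a Spearman rho of 0.283 and a Pearson r of 0.353; genes are not independent replicates, and no p-value was computed. Of 5573 genes with longer treated H3K27ac, 75.1% also had longer H3K4me1, against 66.8% of all 11688. Of 5706 with shorter H3K27ac, 40.4% had shorter H3K4me1, against 32.6% of all. With treated lengths scaled to the untreated total, the shares were 61.1% against 52.6% and 56.7% against 47.5%.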

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

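All 4 lists hold peaks on unplaced scaffolds, which the comparisons above leave out, and these were singled out as signal in data not otherwise used. There were 38 untreated and 18 treated H3K27ac peaks, and 79 untreated and 48 treated H3K4me1 peaks. Most of the drop came from 1 scaffold, with 26 and 10 H3K27ac peaks and 30 and 10 H3K4me1 peaks. No explanation was tested for these peaks.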

How the results depend on the processing

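The alternatives with peaks of at least 200 bp, gene bodies with flanks, the erythroid list without globin genes and lists without their member of largest change were chosen after seeing the data. No paired analysis was possible because each mark and condition has 1 list, which for H3K27ac stands for both replicates, and leaving out a replicate was likewise not possible. Motif content and the gene's 5' end were not run. Of the values under the alternatives, 327 counted as the same. For shares this meant within the counting interval, for ratios within an interval from the chromosome SE, and for counts within 1.5 times. For gene lists it meant no change of sign and no crossing of the central 95%. Of the others, 104 moved, 3 were weaker, 3 stronger and 1 reversed, and these are given here. Of 302 values for gene lists, 5 left the central range and 4 came inside it, 1 of these with its sign reversed. The erythroid membrane, globin and haem list stayed above the central range in all 11 alternatives per mark, from 589 to 2819 bp in H3K27ac and from 613 to 5401 bp in H3K4me1, and the myeloid list below it in all 10, from -424 to -135 bp and from -1232 to -216 bp. Intervals of shares are narrow because peaks are many, so small shifts count as moved. Where a setting removes peaks or asks for more overlap, its own construction changes the share; the cause was not tested otherwise. With treated lengths scaled to the same total, the mean H3K4me1 difference fell from 275 to 30.7 bp over all genes, from 923 to 277 bp for erythroid transcription factors, from 632 to 233 bp for apoptosis, from 874 to 362 bp for cell cycle and from 585 to 76.2 bp for cytokine signalling genes, while the 4 lists kept percentiles within 6 of those before. Depth limits every number here and is unknown.

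With the better-scoring 50% of each H3K4me1 list and the wider 50% of each H3K27ac list the covered length ratio was 0.962 in H3K27ac and 1.04 in H3K4me1. Shared peaks were 86.8% of treated H3K27ac, 79.3% of untreated and 87.4% of treated H3K4me1. H3K27ac lay under 28.8% of untreated and 29.0% of treated H3K4me1 peaks, and 96.9% of untreated-only and 98.7% of treated-only H3K27ac peaks lay over H3K4me1 of both lists. Near gene ends lay 29.7% and 21.6% of such H3K27ac and 12.5% and 12.1% of such H3K4me1 peaks. H3K27ac lay near an end in the untreated or treated list alone at 1138 and 375 genes. The untreated H3K27ac list kept more peaks at a lower width cut, which by itself adds to the 1138. Mean H3K27ac changes were 359 bp for megakaryocyte, 38.2 bp for B cell and -44.4 bp for apoptosis genes.

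With equal peak numbers the number ratio was 1 for both marks by construction, and the length ratios 1.03 and 1.10. Shared were 80.8% and 78.4% in H3K27ac and 80.4% and 75.5% in H3K4me1. H3K27ac lay under 24.2% of untreated H3K4me1 peaks, and 98.2% of untreated-only H3K27ac peaks lay over H3K4me1 of both lists. Near gene ends lay 10.9% of treated-only H3K27ac and 5.36% of untreated-only H3K4me1 peaks, and 239 and 353 genes had H3K27ac in the untreated or treated list alone, and 391 and 516 had H3K4me1, so the order turned in both marks.

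With peaks within 1 kb merged, number ratios were 0.870 and 0.874, and length ratios 0.973 and 1.04. Shared were 76.9% and 87.9% in H3K27ac and 80.2% of treated H3K4me1. H3K27ac lay under 23.3% and 22.7% of H3K4me1 peaks, 95.2% of treated-only H3K27ac peaks lay over both, and near gene ends lay 8.56% of untreated-only H3K27ac and 4.60% and 4.39% of single-condition H3K4me1 peaks. The apoptosis mean was -48.6 bp. On autosomes, 74.7% and 79.9% of H3K4me1 peaks were shared, 23.1% and 23.5% lay over H3K27ac, and 96.4% of untreated-only H3K27ac peaks lay over both. With peaks of at least 200 bp the H3K27ac number ratio was 0.818, with 74.0% and 83.9% shared, 96.6% and 95.2% of single-condition peaks over both, and an apoptosis mean of -2.72 bp.

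Under overlap of 50% of the peak, 67.6% and 75.3% of H3K27ac and 68.1% and 69.4% of H3K4me1 peaks were shared, 6.68% and 6.17% of H3K4me1 peaks lay over H3K27ac, and 94.9% and 93.0% of single-condition H3K27ac peaks lay over both. Under reciprocal overlap of 50% these were 49.9% and 61.8%, 49.6% and 58.4%, 2.98% and 2.71%, and 5.33% and 6.60%. Over 1 kb from gene ends, 60.9% and 73.7% of H3K27ac and 69.3% and 75.3% of H3K4me1 peaks were shared. With gene ends taken as 500 bp, single-condition peaks near them were 6.76% and 6.33% in H3K27ac and 3.32% and 3.15% in H3K4me1, and 585 and 871 genes had H3K4me1 in the untreated or treated list alone, an order that also turned. With 2.5 kb the shares were 18.97%, 16.7%, 10.5% and 10.2%.

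With windows of 20 kb, mean H3K27ac changes were 196 bp for erythroid transcription factors, 254 bp for T cell and -297 bp for apoptosis genes. Mean H3K4me1 changes were -0.667 bp for stem and progenitor, -362 bp for B cell, 742 bp for T cell, 356 bp for stromal and endothelial, and 443 bp for cytokine signalling genes, the last at the 2.22 percentile. Over gene bodies with 5 kb either side, mean H3K27ac changes were 319 bp for erythroid transcription factors, -1300 bp for stem and progenitor, 103 bp for B cell, 36.3 bp for T cell, -60.9 bp for Polycomb, -65.4 bp for apoptosis, -308 bp for cell cycle and -1166 bp for cytokine signalling genes. Stem and progenitor genes then stood at the 0.39 percentile and cytokine signalling genes at 0.47. Mean H3K4me1 changes were -1262 bp for stem and progenitor, 9.18 bp for B cell (reversed), 717 bp for T cell and -1101 bp for cytokine signalling genes, with stem and progenitor genes at the 1.22 percentile and cytokine signalling genes at 0.6. Without the member of largest change, mean H3K27ac changes were 268 bp for megakaryocyte (93.5 percentile), -49.1 bp for apoptosis and -20.4 bp for cell cycle genes, and mean H3K4me1 changes 58.95 bp for T cell and 104 bp for stromal and endothelial genes, so a single member set the sign of the last 4.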

Other observations

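The stitched domains, the comparison with X chromosome copy number, the test of wider peak calls, and the measure of low-scoring peaks in its final form were chosen after results were seen. For the last, a share of at least 75% of untreated-only H3K4me1 peaks in the lower 50% by score had first been set to count for the explanation, and the 90.3% found would have done so. The criterion was changed after this value was seen, because treated-only peaks lie there as often (93.8%) and the test therefore cannot discriminate. For X copy number, an H3K27ac ratio inside the autosome range had first been set to count against the explanation, and the 0.797 found would have done so. This was changed, also after the value was seen, to a ratio above the autosome median, because a loss in part of the cells need not leave the range. For wider peak calls, the percentile of the erythroid list with scaled lengths had been set as the test and would have counted against the explanation, but a factor common to all genes hardly moves such a percentile, so it was dropped.

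Joining H3K27ac peaks of both conditions within 12.5 kb gave 13547 domains, of which 10837 held peaks in both lists, 1795 in the untreated list alone and 915 in the treated list alone. The largest gain was the alpha-globin domain, which takes in Nprl3, whose introns hold the known globin enhancers, and Hba-x, Hba-a1 and Hba-a2, with 8830 bp untreated and 38845 bp treated. It was followed by a domain over Mkln1 and Podxl (28528 bp and 50381 bp), one over Htt, Msantd1 and Rgs12 (16945 bp and 35801 bp), one over Btg2 (10533 bp and 28236 bp), one over Gda, guanine deaminase (3209 bp and 19165 bp), and one over Hipk2 and Tbxas1 (25669 bp and 41260 bp). Among erythroid genes outside the naming rule, Hbb-bs had 1406 bp and 4612 bp of H3K27ac, and Slc4a1, the band 3 anion exchanger, had 0 bp and 1953 bp.

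The largest losses lay over Heg1 and Muc13 (37927 bp and 18024 bp), Tec, a tyrosine kinase gene of blood cells (25895 bp and 6224 bp), Cdk6 (23777 bp and 6009 bp), a region 77126 bp from Max (38851 bp and 22895 bp), Man2a2, Fes, Furin and Blm (38972 bp and 24692 bp), and Hdac7 (24927 bp and 12668 bp). At Cdk6 and Tec the H3K4me1 length was 37509 bp and 29615 bp, and 54218 bp and 39674 bp. The widest untreated domain by covered length was a histone gene cluster on chromosome 13, with 59207 bp and 62289 bp. Those over the erythroid regulators Zfpm1 (53498 bp and 56636 bp) and Bcl11a (52972 bp and 49639 bp) also ranked near the top and differed little between lists.

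Erythroid genes had longer and myeloid genes shorter covered length in the treated lists. By these values, wider peak calls across the whole treated H3K4me1 list do not account for the whole of the erythroid part. The mean difference of the erythroid list, 1943 bp (SE over members 273 bp), lay above the central range of matched random lists, 195 to 1010 bp. That is the list result given above, taken as the criterion after it was seen, so it is not a separate test. With lengths scaled to the same total the erythroid mean was 1369 bp, with 36 longer and 13 shorter. Having fewer mature myeloid cells in the treated culture stays open. Of 10 mature myeloid genes, all members of the myeloid list, 3 had H3K27ac in the untreated list, each with a shorter length in the treated list. At least 5 had been set to count for this explanation and at most 2 against it. The 3 were Csf1r, with 353 bp untreated and 303 bp treated, Csf3r, with 1603 bp and 1403 bp, and Cd68, with 4325 bp and 3525 bp. The differences at Csf1r and Csf3r were small. The others, Mpo, Elane, Prtn3, Ctsg, Lyz1, Lyz2 and Itgam, had 0 bp of H3K27ac in both lists. H3K4me1 was shorter in the treated list at 8 of the 10 and longer at 2, Ctsg and Cd68. A response of the same cells to lower SPI1, to doxycycline or to hairpin expression may also give this pattern. None of these was tested separately, since condition and list coincide.

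Both treated lists held fewer and wider peaks. Peaks that were split in the untreated list and joined in the treated one account for part of the lower number at most, since with peaks within 1 kb joined the H3K4me1 ratio was 0.874 ± 0.011, against 0.849 as deposited and below the 0.95 set beforehand, and the H3K27ac ratio was 0.870, against 0.808. In H3K27ac, 10.8% of treated peaks lay over at least 2 untreated ones, against 3.99% the other way. Narrow peaks near the calling threshold may have been lost: 90.3% of untreated-only H3K4me1 peaks lay in the lower 50% by score, but so did 93.8% of treated-only peaks, so this cannot be told apart from ordinary low-score turnover. The H3K4me1 lists also had different floors: the lowest score was 0.972 untreated and 1.738 treated, and the narrowest peak 203 bp and 303 bp. The scale of the score is not stated, and how much of the lower number these floors account for was not tested. Unequal depth or enrichment stays open as well, as the lists carry neither.

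The X chromosome had a lower H3K4me1 number ratio than any autosome, 0.702 against 0.822 to 0.894 (Y held 12 and 6 peaks and was left out here), and also a lower covered length ratio, 0.994 against 1.04 to 1.11. In the better-scoring 50% of each list its ratio was 0.850, inside the autosome range of 0.821 to 0.900, and its covered length ratio was 1.04, inside 1.02 to 1.10, which is consistent with low-scoring peaks near the calling threshold as the source; the untreated median score was 2.89 on X and 6.23 on chromosome 1. Fewer X copies in the treated culture would also lower H3K27ac, whose X ratio was 0.797, within the autosome range of 0.777 to 0.879 and below its median of 0.807, while its H3K27ac covered length ratio was 0.991, within 0.957 to 1.05 and above the median of 0.989. Both H3K27ac ratios lay inside the autosome ranges and near the medians, on opposite sides, so they show no sign of fewer copies. The H3K4me1 number ratio of 0.850 in the better-scoring 50% also lay near its autosome median of 0.849. A loss in part of the cells need not leave these ranges and is not excluded. The design gives no biological explanation for X to test.

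It was also asked whether both marks change at the same genes. A Spearman rho over 0.3 had been set to count for this and one under 0.1 against it, and the rho of 0.283 across genes lay between them, so the question stays open.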
